A study of Paenarthrobacter sp. TA1.8 with 18 samples.

How the data were processed

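Total RNA of Paenarthrobacter sp. TA1.8 was extracted with the Nucleospin RNA kit, depleted of ribosomal RNA with QIAseq FastSelect and made into directional libraries with NEBNext Ultra II, per the labels' protocols. Sequencing was paired-end at 250 bp on a NovaSeq 6000. The submitters' processing notes name fastp 0.20.1, STAR 2.6.1c, HTSeq 2.0.3 and DESeq2 1.44.0, without settings. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes, or of near-identical copies, could be split or merged in ways that cannot be read from the counts.

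The authors deposited whole-number counts of reads per locus tag, not normalized, for 4747 tags in 18 libraries. Columns were assigned to samples by name. The 18 libraries form 6 groups of treatment and time with 3 biological replicates each, per the series design. The total count per library was 6.29 M to 21.7 M, lowest in the succinate 24 h group.

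Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter and the quasi-likelihood test, in 1 fit over all 18 libraries with 1 coefficient per group. The filter removed 1 tag, which had no counts, and 4746 were tested. The common biological coefficient of variation was 0.20. A tag was called at an adjusted p under 0.05 (Benjamini-Hochberg over tags within a comparison). Standard errors of log2 fold changes were derived from the F statistic. CPM values use TMM-scaled totals, and log2 CPM has a prior count of 2. The 11 comparisons were the treatment difference at each time and averaged over times, the time steps within each treatment and the 3 interactions of treatment and time. This design, the rule for named tags and the first group of alternatives below were fixed before the data were examined.

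The rule for named tags ranked called tags by log2 fold change among those with a mean of 20 CPM or more in the higher group and no overlap between the replicates of the groups, up to 10 in each direction at each time. For time steps and interactions it took the first 3 in each direction. As the file does not pair tags with names, at most 2 tags per direction were printed for each treatment comparison. The 25 gene lists fixed before the data were examined need gene names and were not tested. For the same reason, ribosomal and transfer RNA tags were not set apart, and genes of iprodione hydrolysis, which the rule also named, are not analysed here.

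Tag prefixes, runs of at least 3 consecutive tags and the tag-number trend were taken up after the data were seen. The enrichment of runs was tested with 1000 shuffles. Prefix groups were tested with camera in limma 3.58.1, with the preset correlation of 0.01 and an estimated correlation. With the preset correlation, the FFOCBFNM tags at 8 h (adjusted p = 0.00314) and the HONKHINH tags at 12 h (adjusted p = 0.000657) were also called by camera, and both calls were lost with an estimated one. HCJADMNC holds 96.3% of the tags, and its test mirrors those of the other prefixes. The tag-number trend was a lowess fit with a span of 0.1 within the HCJADMNC prefix, and the median within the other prefixes. Values per library were compared by exact permutation of treatment within time. The 12 measures adjusted together include stretches picked on these same libraries.

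The fit was tested on simulated counts for the 4746 tags with 200 tags changed by a factor of 1.5, 2 or 4. At 8 h, 82.1%, 79.1% and 97.0% of these were recovered in that order, with 10 false calls. At 24 h it was 59.7%, 79.1% and 98.5%, with 11 false calls, and for the interaction from 8 to 12 h 31.3%, 85.1% and 95.5%, with 7. These simulations gave all groups the same spread, which the 24 h libraries did not have.

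Alternatives were DESeq2 1.42.0, RLE scaling, no filter, a filter at a mean of 10 CPM, only the groups compared, the 20 most abundant tags left out, a log2 fold change of 1 or more, a replicate block and each library left out in turn. Added after the data were seen were removal of the tag-number trend, the SD of log2 CPM as a covariate, the 3 libraries with the smallest SD left out, both 24 h groups left out and limma voom with sample quality weights.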

Results

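Paenarthrobacter is a genus of soil bacteria, and iprodione is a dicarboximide fungicide. Per the series design, Paenarthrobacter sp. TA1.8 with iprodione or with succinate, a tricarboxylic acid cycle intermediate, was sampled at 8, 12 and 24 h with 3 biological replicates per condition. The labels call both compounds treatments, and doses are not given in the sources used here. RNA from 18 libraries was sequenced after removal of ribosomal RNA, and the counts cover 4747 locus tags. The file does not pair the tags with gene names or products, so results are given by tag, by runs of consecutive tag numbers and by the letters that open a tag. HCJADMNC opens 4572 tags, EHCEJHHC 87, HONKHINH 52 and FFOCBFNM 36. What these prefixes stand for is not given in the sources used here.

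The total count per library was 16.2 M to 21.7 M outside the succinate 24 h group and 6.29 M to 8.07 M within it. The 20 most abundant tags over all libraries took 21.1% ± 2.53 of the counts with iprodione and 9.14% ± 1.72 with succinate at 8 h, 16.2% ± 2.90 against 14.03% ± 5.47 at 12 h and 16.4% ± 3.92 against 10.4% ± 13.2 at 24 h (SD, n = 3 each; exact permutation of treatment within time, p = 0.0428, and 0.0733 after Benjamini-Hochberg adjustment over 12 measures). The spread of log2 CPM across tags within a library, as its SD, lay between 0.76 and 1.23. It was smallest in succinate 24 h replicate 3, at 0.76, then in succinate 24 h replicate 1, at 0.90, and iprodione 24 h replicate 3, at 0.92. Across genes, which are not independent replicates, replicate pairs had Spearman correlations of log2 CPM from 0.70 to 0.99. Every replicate pair differed by more than counting error, with a chi-square per degree of freedom of 68.8 or more. The 24 h libraries stood apart most: the same 20 tags took from 0.684% to 25.4% of the counts in the succinate 24 h group.

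The comparison at 8 h asks which tags differed between iprodione and succinate at the earliest sampling. With iprodione, 534 of 4746 tags tested were higher and 201 were lower. Of these, 184 rose and 44 fell by 1 or more on the log2 scale. HCJADMNC_04628 had the largest rise, from 48.7 ± 13.01 CPM with succinate to 3850 ± 2411 CPM with iprodione (SD, n = 3 each), a log2 fold change of 6.31 ± 0.65 (SE; adjusted p = 2.78e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). HCJADMNC_00455 followed, at 2358 ± 1178 CPM against 205 ± 28.4 CPM and a log2 fold change of 3.52 ± 0.42 (SE; adjusted p = 0.000112, same edgeR test). Among the falls, HCJADMNC_02986 changed by -1.77 ± 0.47 (SE; adjusted p = 0.0195, same edgeR test) and HCJADMNC_03409 by -1.76 ± 0.32 (SE; adjusted p = 0.00245, same edgeR test). The fall of HCJADMNC_02986 missed the threshold on leaving out iprodione 8 h replicate 1, 2 or 3 or succinate 8 h replicate 2, with adjusted p from 0.0582 to 0.0842 in the same edgeR test. The 10 largest rises ranged from 2.79 to 6.31 and the 10 largest falls from -1.77 to -1.60 on the log2 scale, all with the HCJADMNC prefix.

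Called tags at 8 h lay side by side more often than in shuffles of the calls over all prefixes. In 54 runs of 3 or more consecutive tags called in 1 direction there were 238 tags, against a mean of 19.3 over 1000 shuffles of the called positions within the tag order (permutation p = 0.001, the smallest the shuffles can give). The longest run held 26 tags, all higher with iprodione. The shuffles spread calls over all prefixes, while 74 of the 87 EHCEJHHC tags were called higher. Such a share within a single prefix yields runs by itself, so the p-value does not speak for the HCJADMNC tags alone. The shuffles also treat neighbouring tags as unrelated, while fold changes followed the tag number, as given below. Every other comparison except iprodione against succinate at 24 h reached the same p-value, so it is not particular to 8 h. The count of 735 called tags fell to 474 without iprodione 8 h replicate 1, to 396 without replicate 3, to 430 without succinate 8 h replicate 1 and to 405 without replicate 2. It was 1535 with only the 8 h groups in the fit and 1116 with DESeq2.

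At 12 h, 52 tags were higher and 8 lower with iprodione. Of the rises, 10 lay in a stretch of 10 consecutive tags, from 3 numbers below HCJADMNC_02819 to 6 numbers above it, with a median log2 fold change of 3.06. Another 10 had the EHCEJHHC prefix, and the rest had the HCJADMNC prefix. HCJADMNC_02819 stood at 2896 ± 674 CPM with iprodione and 136 ± 3.10 CPM with succinate (SD, n = 3 each), a log2 fold change of 4.41 ± 0.22 (SE; adjusted p = 4.9e-09, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). HCJADMNC_02822, in the same stretch, changed by 4.16 ± 0.22 (SE; adjusted p = 1.2e-08, same edgeR test). The lower tags included HCJADMNC_00869, at -1.02 ± 0.18 (SE; adjusted p = 0.0059, same edgeR test), and HCJADMNC_01788, at -0.72 ± 0.11 (SE; adjusted p = 0.0026, same edgeR test).

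The stretch was picked, after the data were seen, as the longest run of tags higher by 1 or more on the log2 scale at 12 h, so the 8 h libraries, which are separate, give a check on it. There all 10 tags were called higher too, with a median of 2.02. The mean over the 10 tags was 543 ± 41.7 CPM with iprodione and 129 ± 5.35 CPM with succinate at 8 h, and 1367 ± 337 against 136 ± 2.27 CPM at 12 h (SD, n = 3 each). At 24 h it was 168 ± 7.12 against 163 ± 9.97 CPM, and the log2 fold changes of the 10 tags lay between -0.17 and 0.34 with a median of 0.05. Among the 5 tags on either side, 1 of 10 was called at 8 h and 4 of 10 at 12 h.

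**Figure D1:**
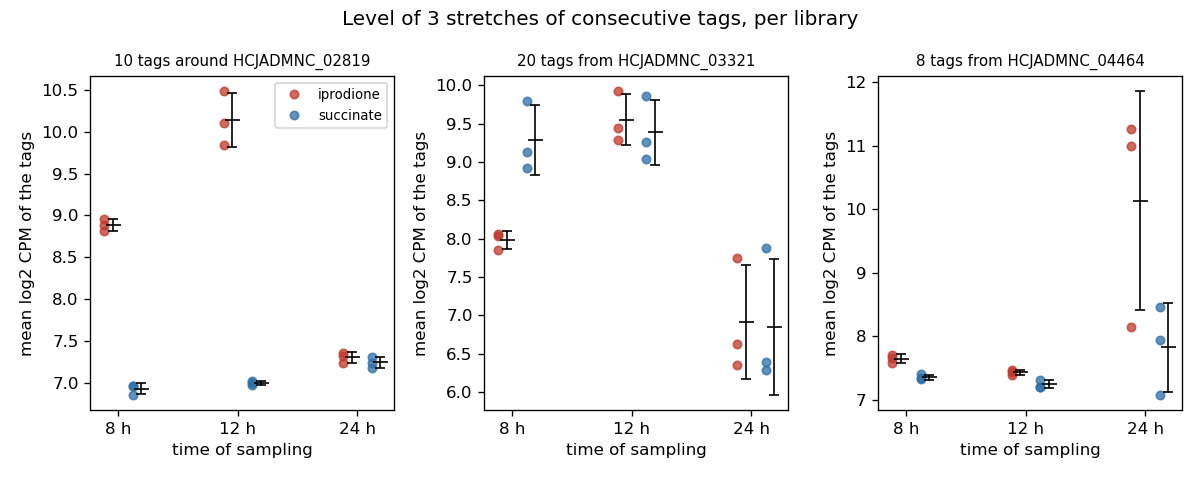
Each panel plots the mean log2 CPM of a stretch of consecutive tags in each library (points, red for iprodione and blue for succinate) by sampling time, with the group mean and SD beside the points (n = 3). In the left panel the 10 tags around HCJADMNC_02819 are higher with iprodione at 8 and 12 h and overlap at 24 h, the other panels show the 20 tags from HCJADMNC_03321 (middle) and the 8 tags from HCJADMNC_04464 (right), where 1 iprodione 24 h library lies far below the others.

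Higher calls at 8 and 12 h shared 34 tags, where independent lists of 534 and 52 tags would share 5.85. Lower calls shared 5, where independent lists would share 0.34. The count of 60 at 12 h was 38 without iprodione 12 h replicate 2, 38 without succinate 12 h replicate 1 and 33 without succinate 12 h replicate 3. It was 352 with only the 12 h groups in the fit and 260 with DESeq2.

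At 24 h, 2 tags were called, both higher with iprodione and both with the EHCEJHHC prefix. EHCEJHHC_00061 stood at 176 ± 41.8 CPM with iprodione and 89.9 ± 10.3 CPM with succinate (SD, n = 3 each), a log2 fold change of 0.97 ± 0.14 (SE; adjusted p = 0.0203, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). EHCEJHHC_00084 changed by 0.57 ± 0.09 (SE; adjusted p = 0.0362, same edgeR test). Without iprodione 24 h replicate 1, iprodione 24 h replicate 2 or succinate 24 h replicate 1, their adjusted p lay between 0.0665 and 0.195 in the same edgeR test. With only the 24 h groups in the fit it was 0.902 for both, at log2 fold changes of 0.99 and 0.58, and the count was 0, with 98 tags at an unadjusted p under 0.05. At an unadjusted p under 0.05, edgeR gave 821 tags, where 237.3 would be reached by chance, and DESeq2 called 157 tags higher and 51 lower. The count was 0 without iprodione 24 h replicate 1 or 2 or succinate 24 h replicate 1, 980 without iprodione 24 h replicate 3, 1190 without succinate 24 h replicate 2 and 24 without succinate 24 h replicate 3. Libraries at this time differed within a group in their spread of log2 CPM, from 0.92 to 1.14 with iprodione and from 0.76 to 1.23 with succinate. With limma voom and sample quality weights, an alternative added after the data were seen, 1845 tags were called.

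Averaged over the 3 times with equal weight, 523 tags were higher and 342 lower with iprodione, and 74 of them rose by 1 or more on the log2 scale. All 10 tags around HCJADMNC_02819 were higher, with a median log2 fold change of 1.78. The count of 865 was 559 without iprodione 8 h replicate 3, 551 without iprodione 12 h replicate 2, 539 without iprodione 24 h replicate 2, 1517 without iprodione 24 h replicate 3 and 1875 without succinate 24 h replicate 2. It was 1337 with DESeq2.

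The EHCEJHHC tags moved together. Of 87, 74 were called higher with iprodione at 8 h, 10 at 12 h, 2 at 24 h and 79 in the average over the 3 times. Their median log2 fold changes were 0.65, 0.47, 0.35 and 0.51 in that order, and all 87 members lay above 0 at 8 h, all 87 at 12 h and 81 at 24 h. A camera set test with an estimated correlation gave adjusted p = 0.00184 at 8 h, 0.00187 at 12 h and 0.00878 at 24 h over the 4 prefixes. The 10 calls at 12 h were 4 without iprodione 12 h replicate 2, succinate 12 h replicate 1 or succinate 12 h replicate 3, and 54 with DESeq2. The 2 calls at 24 h were 0 without iprodione 24 h replicate 1 or 2 or succinate 24 h replicate 1, 11 without iprodione 24 h replicate 3, 21 and 22 without succinate 24 h replicates 2 and 3, and 20 with DESeq2. Adjusted over the list alone, which was chosen on these libraries, 81, 69 and 32 tags passed at 8, 12 and 24 h. The median log2 CPM of these tags was 6.18 ± 0.06 with iprodione and 5.46 ± 0.16 with succinate at 8 h, 6.11 ± 0.08 against 5.62 ± 0.04 at 12 h and 5.73 ± 0.09 against 5.25 ± 0.22 at 24 h (SD, n = 3 each). Across all times, an exact two-sided permutation test of treatment within time gave p = 0.00025, the smallest its 8000 arrangements can give, and 0.003 after Benjamini-Hochberg adjustment over 12 measures. At any 1 time, 3 libraries against 3 cannot give an exact p below 0.1, and this was the value at each of the 3 times. Medians of the FFOCBFNM tags were 0.21, -0.04 and -0.02 at 8, 12 and 24 h, with camera adjusted p = 0.432, 0.769 and 0.985 with an estimated correlation. Those of the HONKHINH tags were -0.04, -0.17 and -0.04, with camera adjusted p = 0.806, 0.286 and 0.985 with an estimated correlation, and at 8 and 24 h that test pointed upward against the sign of the median. These prefix groups were chosen after the data were seen.

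**Figure D2:**
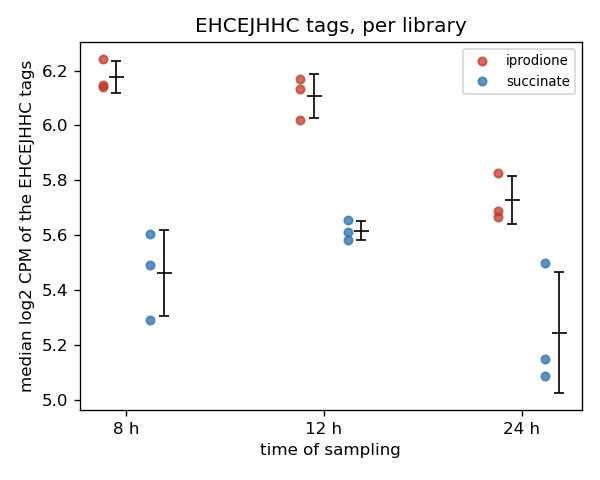
Median log2 CPM of the EHCEJHHC tags in each library (points, red for iprodione and blue for succinate) by sampling time, with the group mean and SD beside the points (n = 3). At each time the 3 iprodione libraries lie above the 3 succinate libraries, with group means of 6.18 against 5.46 at 8 h and 5.73 against 5.25 at 24 h.

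Fold changes among the HCJADMNC tags also followed the tag number. Of tags in the outer part of the numbering, nearer to either end than to the middle, 307 were higher and 18 lower with iprodione at 8 h, while in the inner part 141 were higher and 183 lower. Within a library, the slope of log2 CPM, relative to each tag's mean over all libraries, from the middle of the numbering to its ends was 0.49 ± 0.03 with iprodione and 0.15 ± 0.06 with succinate at 8 h, 0.24 ± 0.05 against -0.06 ± 0.06 at 12 h and -0.42 ± 0.07 against -0.40 ± 0.03 at 24 h (SD, n = 3 each). An exact two-sided permutation test of treatment within time gave p = 0.00375, and 0.015 after Benjamini-Hochberg adjustment over 12 measures. Across genes, which are not independent replicates, the Spearman correlation of log2 fold change with distance from the middle was 0.36 at 8 h, 0.55 at 12 h and -0.06 at 24 h. Rotating the numbering against the fold changes in each of its 4571 steps gave permutation p = 0.0632, 0.00766 and 0.351, or 0.11, 0.0577 and 0.387 after Benjamini-Hochberg adjustment over 11 comparisons, so that none of the 3 passed the threshold of 0.05 in this test. With a smooth trend along the numbering and the median of each other prefix removed from each library, an alternative added after the data were seen, 434 tags were called at 8 h, 40 at 12 h and 0 at 24 h by edgeR, where 810 had an unadjusted p under 0.05 and DESeq2 called 208 without that removal.

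**Figure D3:**
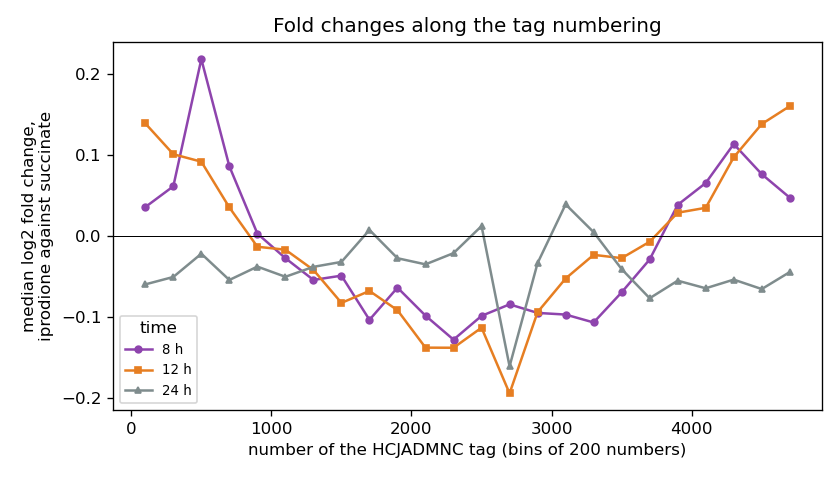
Median log2 fold change of iprodione against succinate in bins of 200 tag numbers of the HCJADMNC prefix, at 8 h (circles), 12 h (squares) and 24 h (triangles). The 8 and 12 h lines lie above 0 toward both ends of the numbering and below 0 in the middle, with medians of 0.05 in the outer and -0.09 in the inner part at 8 h.

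The time steps ask how each treatment changed over sampling. With iprodione, 321 tags rose and 415 fell from 8 to 12 h, and 1066 rose and 976 fell from 12 to 24 h. With succinate, 60 rose and 8 fell from 8 to 12 h, and 259 rose and 276 fell from 12 to 24 h. HCJADMNC_04628 rose with succinate from 48.7 ± 13.01 CPM at 8 h to 2509 ± 1279 CPM at 12 h (SD, n = 3 each; log2 fold change 5.69 ± 0.63 SE, adjusted p = 0.0012, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It then fell to 56.7 ± 30.7 CPM with succinate and, from 4142 ± 1119 CPM, to 46.3 ± 3.63 CPM with iprodione at 24 h (SD, n = 3 each). The 10 tags around HCJADMNC_02819 fell by a median of 2.82 on the log2 scale from 12 to 24 h with iprodione, while with succinate their log2 fold changes lay between -0.03 and 0.17 from 8 to 12 h and between 0.12 and 0.36 from 12 to 24 h. The EHCEJHHC tags had median log2 fold changes of -0.43 with iprodione and -0.27 with succinate from 12 to 24 h, where edgeR called 54 of 87 lower and 3 higher with iprodione, and 12 lower with succinate. Camera gave adjusted p = 0.126 and 0.0542 with an estimated correlation, and 9.35e-11 and 1.08e-13 with the preset one.

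Other stretches changed at 24 h. The longest run of tags that fell by 1 or more from 12 to 24 h with iprodione held 20 tags from HCJADMNC_03321. Its mean went from 875 ± 218 to 143 ± 83.3 CPM with iprodione, and from 803 ± 246 to 146 ± 105 CPM with succinate (SD, n = 3 each), where 19 of the 20 were called lower by edgeR over all libraries and 20 by DESeq2. With only the groups compared in the fit, edgeR called 0 of the 20 with succinate, with 19 at an unadjusted p under 0.05 and a median log2 fold change of -2.47 against -2.48 over all libraries. At 8 h, 10 of these 20 tags were lower with iprodione, at 279 ± 24.1 against 756 ± 272 CPM. The number was 2 on leaving out any 1 of the 3 iprodione 8 h libraries, 1 without succinate 8 h replicate 2 and 5 without succinate 8 h replicate 3. The change of this difference from 8 to 12 h had a median of 1.54 on the log2 scale, and edgeR called 0 of the 20 tags over all tags tested, with 13 at an unadjusted p under 0.05 and 8 adjusted over the list alone. DESeq2 called 3. The list was chosen on the iprodione 12 h libraries among others, which this test uses again. The longest run of rises of that size from 12 to 24 h with iprodione held 8 tags from HCJADMNC_04464, with a median log2 fold change of 3.57. Their mean was 2980, 3750 and 326 CPM in iprodione 24 h replicates 1, 2 and 3, against 192 ± 2.05 CPM at 12 h (SD, n = 3). With succinate the mean was 305 ± 156 CPM at 24 h (SD, n = 3), and the log2 fold changes from 12 h lay between -0.12 and 1.74.

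The 736 calls from 8 to 12 h with iprodione were 439 without iprodione 8 h replicate 1 and 393 without iprodione 12 h replicate 1. The 68 calls of that step with succinate were 1 on leaving out any 1 of the 3 succinate 8 h libraries, 13 without succinate 12 h replicate 1 and 27 without replicate 3. The 535 calls of the later step with succinate were 190 without succinate 12 h replicate 1, 235 without succinate 12 h replicate 3 and 1020 without succinate 24 h replicate 2. With only the groups compared in the fit, this later step with succinate had 9 calls, all lower, with 881 tags at an unadjusted p under 0.05, and DESeq2 gave 986 calls. The other 3 steps had 1514 (iprodione, 8 to 12 h), 1663 (iprodione, 12 to 24 h) and 363 calls (succinate, 8 to 12 h) with only the groups compared, and 1067, 2389 and 212 with DESeq2.

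**Figure D4:**
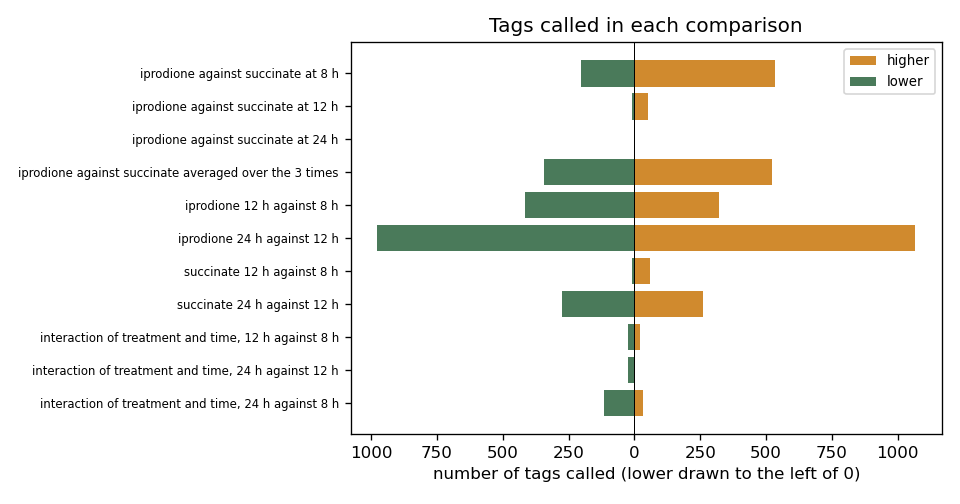
Number of tags called in each of the 11 comparisons, with higher calls drawn to the right of 0 and lower calls to the left. The longest bars are those of iprodione 24 h against 12 h, with 1066 higher and 976 lower.

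The interaction of treatment and time tests whether the difference between treatments itself changed. From 8 to 12 h, 21 tags had a larger and 24 a smaller difference of iprodione over succinate. From 12 to 24 h these were 2 and 26, and from 8 to 24 h 33 and 114. The 10 tags around HCJADMNC_02819 took part in each of the 3 tests, with 8 of 10 called larger in the first and all 10 called smaller in the second and the third. The stretch was picked on the 12 h libraries, which the first and the second test use again, so only the third, from 8 to 24 h, is separate from that choice. HCJADMNC_02819 and HCJADMNC_04628 were likewise named for their changes at 12 h and at 8 h. For HCJADMNC_02819 itself the difference grew by 1.62 ± 0.27 (SE; adjusted p = 0.00961) and then changed by -4.07 ± 0.28 (SE; adjusted p = 4.39e-07), both by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For HCJADMNC_04628 the difference changed by -5.58 ± 0.78 from 8 to 12 h (SE; adjusted p = 0.00273, same edgeR test). The EHCEJHHC tags had medians of -0.18, -0.13 and -0.31 in the 3 tests, where edgeR called 0, 0 and 5 of 87, all 5 smaller, with 10, 6 and 18 at an unadjusted p under 0.05. DESeq2 called 1, 1 and 8 smaller, and 1 larger from 8 to 24 h.

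These counts moved with single libraries and with the fit. With only the groups compared they were 490, 19 and 20 in the order above, and with DESeq2 236, 128 and 476. The 45 calls from 8 to 12 h were 25, 72 and 28 without iprodione 8 h replicates 1, 2 and 3, 27 without iprodione 12 h replicate 1, 28 and 20 without succinate 8 h replicates 1 and 2, and 24 without succinate 12 h replicate 3. The 28 calls from 12 to 24 h were 414 without iprodione 24 h replicate 3 and 259 without succinate 24 h replicate 2. The 147 calls from 8 to 24 h were 69 and 65 without iprodione 8 h replicates 1 and 3, 53, 86 and 653 without iprodione 24 h replicates 1, 2 and 3, 69, 42 and 83 without succinate 8 h replicates 1, 2 and 3, and 403 without succinate 24 h replicate 2.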

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

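The tests of label exchange, of replication, of the copies of the EHCEJHHC tags and of scaling were chosen only after the result was seen. The other tests were set before their results, but those of evenness and of the tag-number trend came after the data were seen. For the abundant genes and for the splits of the interactions, the reading was changed to undecided after the results were seen. By the bounds first set, abundant genes would have been argued against, and chance would have stayed open for the interactions.

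The difference between treatments changed with time, by an interaction test, for 45 tags from 8 to 12 h, 28 from 12 to 24 h and 147 from 8 to 24 h. For HCJADMNC_04628, high in both treatments at 12 h, the log2 difference changed by -5.58 from 8 to 12 h (adjusted p = 0.00273) and by -6.59 from 8 to 24 h (adjusted p = 0.000269). For HCJADMNC_00455 it changed by -3.30 from 8 to 24 h (adjusted p = 0.00588) and for HCJADMNC_03409 by 1.78 (adjusted p = 0.043). These tags were named for their differences at 8 h, which these tests use again, so that choice favours a smaller difference later.

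HCJADMNC_02819 and HCJADMNC_02822, in 1 stretch of 10 tags, gained 1.62 and 1.73 from 8 to 12 h (adjusted p = 0.00961 and 0.00786). From 12 to 24 h they changed by -4.07 and -4.10 (adjusted p = 4.39e-07 and 4.98e-07), and from 8 to 24 h by -2.45 and -2.38 (adjusted p = 0.000142 and 0.000237). For HCJADMNC_00869 the difference changed by 1.17 from 12 to 24 h (adjusted p = 0.0493) and by 1.05 from 8 to 24 h (adjusted p = 0.0344). For HCJADMNC_01788 it changed by 1.02 (adjusted p = 0.00394) and 0.68 (adjusted p = 0.033) over the same spans. All are adjusted p-values of edgeR's quasi-likelihood test. The tags of this paragraph were named for their differences at 12 h, so only their changes from 8 to 24 h are separate from that choice.

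Other splits of the same libraries test whether a count could come from any grouping. For the average over the 3 times, 1 of 100 splits, the real one with 865 tags, reached that count, and the highest other gave 859. The share of splits is under the bound of 0.05 set beforehand for excluding chance. It rests on the rank alone, as the margin is small beside the range of 539 to 1875 on leaving out 1 library. The count itself does not stand clear of other groupings. For the 3 interactions, 4, 8 and 7 of 33 splits called as many as the real 45, 28 and 147 tags, with highest other counts of 276, 1561 and 2538. These splits do not decide for the interactions, since relabelling at 1 time can turn the difference between treatments into an interaction. From 8 to 12 h, all 3 other splits that reached the real count kept or exchanged every label at 1 time, and the 25 that mixed labels at both gave 0 calls. Mixing puts the treatment difference into the spread within groups, which works against calls, so these 0 calls do not speak for an interaction. From 12 to 24 h and 8 to 24 h, splits that mixed labels at both times gave up to 1561 and 1162 calls, which points to a structure of the libraries at 24 h. For the comparisons of 3 libraries with 3, 10 splits are too few for a share under 0.05. The real and highest other counts were 735 and 0 at 8 h, 60 and 0 at 12 h and 2 and 2590 at 24 h, where 4 splits reached the real count. They were 736 and 1, then 2042 and 0 for the steps with iprodione, and 68 and 0, then 535 and 97 with succinate, where 1 split, the real one, reached the count.

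At 24 h few tags were called in the main fit, and the split with 2590 calls set iprodione 24 h replicates 1 and 2 with succinate 24 h replicate 2 against the rest. The lower depth of the succinate libraries is argued against as the cause, since with every library thinned to the shallowest total 693 tags were called at 8 h. An exchange of the labels of iprodione 24 h replicate 3 and succinate 24 h replicate 2 is argued against by the EHCEJHHC tags, whose median log2 CPM was 0.68 higher in the first than in the second. Unequal evenness of the libraries within each group stays open, as a covariate for the SD of log2 CPM gave 30 calls at 24 h. Limma voom with sample quality weights gave 1845, and edgeR gave 1190 without succinate 24 h replicate 2, so the small count depends on the fit. Neither value tells evenness from other differences between the libraries. The highest count of any tag was 7937 in succinate 24 h replicate 3 and 647396 in succinate 24 h replicate 2. Unequal shares of reads from DNA in the 24 h libraries were not tested. A true variation in state between the cultures of a group was not tested either.

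At 8 h the fold changes followed the tag number. The 20 most abundant tags did not themselves carry the slope, which was 0.33 without them and 0.34 with them. Their removal hardly moved the scaling, so this test does not decide on an effect through scaling. A change of scaling shifts all tags of a library alike, which by itself gives no slope along the numbering. Gene copies that differ with replication stay open, if the numbering runs from the origin, as the slope within libraries fell from 8 to 24 h in both treatments. Calls at 8 h among HCJADMNC tags were 649, or 1.52 times the 428 with the trend removed, but any cause of such a trend would lower that count. Reads from DNA in the libraries also stay open, since the quieter HCJADMNC tags, with the trend removed, varied between libraries by a median SD of 0.14. Few tags were silent in any library. The 1st percentile over tags lay between 18.9 and 31.4 CPM, against library medians of 129 to 137 CPM. These values do not tell reads from DNA from low transcription. In the rotation test the 8 h trend had an adjusted p of 0.11, so the place of the ends itself is not shown.

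The EHCEJHHC tags rose together with iprodione. Scaling is argued against, as in 3 of 3 comparisons the median of another small prefix lay below 0.1. At 8 h this held for the HONKHINH tags, at -0.04, but not for FFOCBFNM. Its median was 0.21, with 35 of 36 members above 0, against 0.65 for EHCEJHHC. A difference in the copies of all EHCEJHHC tags together, as for a separate replicon, is a candidate explanation. The interquartile range of their log2 fold changes at 12 h was 0.16 against a median of 0.47. It was 0.09 for FFOCBFNM and 0.21 for HCJADMNC, and at 24 h the EHCEJHHC members ranged from -0.50 to 1.84. Such a range cannot tell copies from a shared change in transcription. The sources used here do not say what the prefix stands for, and a shared change in transcription was not tested. Whether reads from DNA contribute to the shift of the EHCEJHHC tags was not tested either.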

How the results depend on the processing

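The removal of the tag-number trend, the SD covariate, the omission of libraries or groups other than 1 at a time and voom weights were chosen only after the data were seen. Orders are 8 h, 12 h, 24 h, the average, iprodione 12 against 8 h and 24 against 12 h, the same steps with succinate, and the interactions from 8 to 12, 12 to 24 and 8 to 24 h. Of the counts of calls, 50 of 96 with 1 library left out and 68 of 136 under the other alternatives stayed within 1.5 times. The log2 fold changes of the named tags kept sign and side of the threshold in 50 of 60 and 113 of 118, and the others kept the sign. The medians of tag groups kept within replicate spread in 364 of 384 and 463 of 500. No filter, the 10 CPM filter, the 20 tags left out and the replicate block moved no count beyond 1.5 times, and RLE scaling only 24 h, to 9.

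With 1 library left out, counts ranged over 396 to 633, 33 to 67, 0 to 1190, 539 to 1875, 393 to 573, 1496 to 2266, 1 to 86, 190 to 1020, 20 to 72, 21 to 414 and 42 to 653. The lone values below moved by over 1.5 times, and a comparison missing from a list stayed within that or was not run. DESeq2 gave 1116, 260, 208 and 1337, then 212 and 986 for the steps with succinate and 236, 128 and 476 for the interactions. With only the groups compared it was 1535, 352 and 0 (98 at an unadjusted p under 0.05 by edgeR, and 208 calls by DESeq2 over all libraries), then 1514 for iprodione 12 against 8 h, 363 and 9 with succinate, and 490 and 20 for the first and last interaction. With the trend removed it was 434, 0 at 24 h (810 unadjusted), 334 for the average, 824 for iprodione 24 against 12 h, 37 and 188 with succinate and 79 for the last interaction. That removal takes out each prefix's median and so brought the EHCEJHHC medians to -0.031 at 8 h and -0.0075 in the average. The SD covariate gave 257 at 12 h, 30 at 24 h, 1220 for iprodione 12 against 8 h, 282 and 1448 with succinate and 285, 87 and 617. Without the 3 libraries of smallest SD it was 1793, 475, 805, 1488, 1725, 597 and 1849 with succinate, and 472, 707 and 1230, and the lone succinate 24 h library left is assumed to vary like the others. Without both 24 h groups it was 1702, 506, 1729, 562 and 490. Voom weights gave 1745, 949, 1845, 2362, 1840, 919, 1300, 532, 1196 and 1245. With a log2 fold change of 1 or more required it was 228, 23, 0 (821 unadjusted), 74, 229, 411, 42 and 156, then 24 and 60 for the first and last interaction. Omitting heterogeneous 24 h libraries raised the counts at 8 and 12 h, and the cause of the other moves was not tested. The alternative keeping ribosomal and transfer RNA tags, and the gene list alternatives, were not run, as no names are given. Across genes, deviations of equal replicate numbers at 1 time had r from -0.191 to 0.438, with 4 of 9 above 0.1. Over all pairs of groups, 14 of 45 with equal numbers and 35 of 90 with different numbers lay above 0.1. Replicate numbers thus gave no sign of paired libraries, which 3 replicates per group cannot exclude. Thinned to the shallowest total, 693 tags were called at 8 h.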

Other observations

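From 12 to 24 h, the 51 HONKHINH tags tested had median log2 fold changes of -0.14 with iprodione and -0.30 with succinate, with camera adjusted p = 0.481 and 0.0508 with an estimated correlation, and 0.0157 and 1.78e-11 with the preset one. The 36 FFOCBFNM tags had medians of -0.12 and -0.15, with camera adjusted p = 0.563 and 0.278 with an estimated correlation, and 0.0798 and 0.000871 with the preset one. By edgeR, 9 and 12 HONKHINH tags and 7 and 6 FFOCBFNM tags were called lower with iprodione and succinate, and 3 FFOCBFNM tags were called higher with iprodione.

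At 24 h, the level of the 8 tags from HCJADMNC_04464 against succinate had a median log2 fold change of 2.85, and edgeR called 0 of them over all tags tested. At an unadjusted p under 0.05 it was 8, as it was adjusted over the list alone, which was chosen on the iprodione libraries, and DESeq2 called 8. Without iprodione 24 h replicate 3 or succinate 24 h replicate 2, edgeR called 8. The groups overlapped: the median log2 CPM of the 8 tags was 11.9, 12.1 and 8.39 in iprodione 24 h replicates 1, 2 and 3. In succinate 24 h replicates 1, 2 and 3 it was 8.73, 8.09 and 6.95. An exact permutation test at 24 h gave p = 0.2, where 0.1 is the smallest possible. Across genes, which are not independent replicates, the Spearman correlation of log2 CPM was 0.94 between iprodione 24 h replicate 3 and succinate 24 h replicate 1, and 0.92 between succinate 24 h replicate 2 and each of iprodione 24 h replicates 1 and 2. Between succinate 24 h replicates 2 and 3 it was 0.70.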
